A study of Drosophila melanogaster with 4 samples.

How the data were processed

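RNA of Drosophila melanogaster pole cells, the germ-line precursors of the embryo, was measured on 4 Agilent arrays with 2 colours each. Per the labels, the cells were sorted by FACS from embryos of stages 8 to 14 on an EGFP-Vas germ-line marker, and 100 ng of total RNA was amplified and labelled. Per the series' design text, the embryos carried a UAS transgene for the kinase Tao in the form D168A or D168D, from the fathers. The mothers either brought the nosGal4:VP16 driver (driven) or were of the yw strain (non-driven). Each array set driven against non-driven cells of 1 form, and each form had 1 array with the driven RNA in Cy3 and 1 with it in Cy5. The 2 arrays of a form carry the same number in the labels and the design text names 1 driven and 1 non-driven source per form, so they were treated as a technical dye swap and as 1 replicate.

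The deposited values are a log10 ratio per feature, made by the authors with Agilent Feature Extraction 7.1, per the submitters' processing notes. The settings of that software, its background correction and its dye normalization are not given in the sources used here. The log base is not stated beside the values. It was taken from the software, whose ratio is a log10, and from the limit of 2 in either direction, which on that scale is the software's 100-fold limit. Dye orientation was read from the labels. Before the data were examined it was assumed that the arrays with driven RNA in Cy3 would need their sign turned, but the deposited values are already driven over non-driven on all 4 arrays. On both arrays with driven RNA in Cy3 every zero is written as a negative zero (446 and 583 features), as a change of sign leaves it. In addition, 314 unnamed features that exceed 10-fold on all 4 arrays have opposite signs in the 2 dye orientations. No sign was therefore turned. Over genes, the array medians were 0.00078 and 0.0140 on the log2 scale for D168A with driven RNA in Cy3 and in Cy5, and 0 and -0.0022 for D168D. Whether the authors centred the values is unknown. No spot intensities were used here, so signal over background is unknown, and the number of arrays limits the precision.

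Of 22575 features, 17328 had 1 gene symbol in the platform annotation, 326 had several and 4921 had none, and only the first kind was used. By gene ID, 17324 of the probes matched the RefSeq gene table of the Release 6 plus ISO1 MT assembly, and 0 symbols changed. No coordinates were used. The probes were averaged into 10804 genes, of which 5273 had 1 probe, 4814 had 2 and 717 had more. The deposited log10 ratios were converted to log2, and a gene's value in a form is the mean of its 2 arrays. The error given after ± is the distance of either array from that mean, which covers hybridisation and dye and no biological variation. A gene-specific dye effect cancels in the mean of both orientations.

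With 1 replicate per form, no p-value was computed within a form. A gene was called higher or lower in driven cells where it differed at least 2-fold in the same direction on both arrays. The same rule with the sign of the arrays with driven RNA in Cy3 restored counts genes that reach the threshold in opposite directions on the arrays as used. A dye effect gives that pattern, so the count measures disagreement between arrays and not calls that dye can produce. The difference between the forms was taken within each dye orientation and had to reach 2-fold in both. A dye effect that both forms share cancels in that difference. The contrast common to both forms was the only one tested, with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 2 pair means against 0, with 1 residual degree of freedom per gene, two-sided, and Benjamini-Hochberg adjusted p under 0.05. Nothing in the labels says that the forms' cells came from more than 1 collection each, so these p-values measure the spread between the 2 pairs. That spread is moderated by eBayes towards the spread over all genes, so it is not that of the named gene alone. The test was tried on simulated data of 10804 genes for this contrast. It recovered 95 of 100 genes planted at 2-fold and 100 of 100 at 4-fold, with 0 of 10604 unchanged genes called. In these simulated data the deviations of the 2 pairs were equal and opposite, so they cancelled in the tested mean. The 0 calls were therefore fixed in advance, and the recovery says nothing of deviations that do not cancel. The rule of size recovered 20 and 19 of 100 at 2-fold in the forms D168A and D168D and 100 of 100 at 4-fold in each. It called 1 unchanged gene in each. The simulated deviations of a form came from the difference between the forms and were shuffled over genes apart from the dye deviations. Variation common to both forms and any tie between these deviations within a gene were thus left out. These calls are therefore no measure of false calls among the real genes.

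Gene lists were fixed before the data were examined, and 22 had 5 or more measured members. Each list's median log2 ratio was placed among those of 10000 random lists of the same size, drawn from all named genes. The lists could not be matched on expression, since the values hold no level, and the percentile describes these hybridisations and is not a p-value. The genes named in the text were set by a rule: Tao; up to 12 genes with the largest and 12 with the smallest mean among those called in a form, and 8 in each direction for the difference; up to 4 called members per list; the 10 of smallest p in each direction for the common contrast; and the pro-apoptotic genes hid, rpr, grim and skl. hid and rpr had no probe with a single symbol and were not analysed here. Genes named outside that rule are marked as chosen after their values were seen.

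Alternatives were thresholds of 1.5-fold and 3-fold, the mean of both arrays alone, centring on each array's median, counting by probe, leaving out genes with a deposited 0, subtracting the other form's dye effect, either dye orientation alone, limma over the 4 arrays as if they were replicates, the other log base, robust variance moderation, and the mean of a list in place of its median. A demand that every probe of a gene pass, and lists without called members, were added after seeing the data. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.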

Results

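Pole cells were compared between embryos that expressed a transgene of the kinase Tao under the maternal nosGal4:VP16 driver and embryos that carried the transgene without the driver. Tao is a Ste20-family kinase that acts upstream of Hippo signalling and on microtubules. The labels call the form D168A dominant negative. For D168D the series title speaks of a wild-type form, the sample descriptions of overexpression, and the sample titles carry the tag gof. Each form was hybridised on 2 arrays of opposite dye orientation, which make 1 replicate, so values within a form have no replicate check. All ratios are driven over non-driven, on the log2 scale, and ± gives the distance of either array from the mean of its form. In both forms the driven and non-driven cells also differ in the genotype of their mothers, which cannot be told apart from expression of the transgene.

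The targeted gene came first, as a check of the labels and of the direction. Tao (NCBI Gene 32948) was 7.5-fold higher in driven cells with D168A (2.91 ± 0.07) and 8.08-fold higher with D168D (3.01 ± 0.02). Its 2 probes gave 2.92 and 2.89 with D168A and 3.16 and 2.87 with D168D. The difference of D168A from D168D was -0.11 ± 0.04. Whether the probes separate the transgene from the endogenous transcript is unknown, since no probe sequence was used here.

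The first comparison asked how expression of the dominant-negative form D168A affected RNA levels in pole cells. Beside Tao, the genes with the highest ratios were CG9447 (2.64 ± 0.97, 6.23-fold), Atx-1, the fly relative of ataxin 1 (2.10 ± 0.25), CG11626 (1.94 ± 0.29) and bnb (1.90 ± 0.12). Pmvk, a phosphomevalonate kinase of the mevalonate pathway, was at 1.47 ± 0.40, CG10384 at 1.46 ± 0.28 and CG6287 at 1.39 ± 0.31. Qsox3, a sulfhydryl oxidase, was at 1.38 ± 0.04, Sod3, an extracellular superoxide dismutase, at 1.38 ± 0.02, lig at 1.36 ± 0.04 and the glutathione S-transferase GstE1 at 1.21 ± 0.12. The glycosyltransferase Ugt50B3 was lower in driven cells, at -1.04 ± 0.04. A probe of Ugt50B3 was at -0.79 on the Cy3-driven array, so the call is lost where every probe must pass.

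In all, 16 of 10804 genes were at least 2-fold higher on both D168A arrays and 1 was lower. The others among the higher genes, named after their values were seen, were Gr98b, CG15353, CG7653 and CG32488. With the sign of the Cy3-driven array restored, 7 genes met the same rule. Probes of a gene differed in some cases: with D168A, the probes of CG6287 gave 3.17 and -0.40, those of Pmvk -0.10 and 3.04, and those of lig 2.63 and 0.09. For Sod3 they gave 1.81 and 0.94, so that its gene mean passed while the lower probe missed the threshold. Across all genes, the 2 D168A arrays correlated at r = -0.10, and the median distance of an array from the mean was 0.11.

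Among the gene lists, the early patterning genes, which include the gap and pair-rule genes, lay above the random lists with D168A. Their median was 0.14, with 20 of 26 measured members above 0 and a percentile of 99.97, although 0 of them met the rule of size. The egg-shell list lay below, with a median of -0.10 over 9 members (percentile 1.78). That list took genes by name and also holds genes that are not egg-shell genes, among them Cp190 and Cp110. On single arrays, the early patterning list was at percentile 96.4 with driven RNA in Cy3 and 100 with it in Cy5, and the egg-shell list at 50.6 and 0.31, so both left the central 95% only on the Cy5-driven array. By its mean in place of its median, the egg-shell list was inside the central 95%, at percentile 7.76.

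The second comparison put the same question for the form D168D. Beside Tao, the highest ratios were those of Atx-1 (2.46 ± 0.66, 5.52-fold), bnb (1.95 ± 0.02), Drep1 (1.89 ± 0.03) and tll (1.74 ± 0.10). Drep1 belongs to the DNA fragmentation factor family and tll encodes a nuclear receptor of the terminal gap class. Brd, of the Bearded family of Notch regulators, was at 1.72 ± 0.02, CG7840 at 1.69 ± 0.14, Pmvk at 1.63 ± 0.29, CG6287 at 1.63 ± 0.37 and Sod3 at 1.61 ± 0.06. CG15628 was at 1.32 ± 0.22 and Dlg5, a membrane-associated guanylate kinase homologue, at 1.25 ± 0.23. Ccdc114 was lower in driven cells, at -1.07 ± 0.06.

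With D168D, 17 genes were at least 2-fold higher on both arrays and 1 was lower, against 5 that met the rule with the sign restored. The rest of the higher genes, named after their values were seen, were CG12159, CG32243, Mabi, Lapsyn and CG13653. The probes of CG6287 gave 3.38 and -0.12 with D168D, those of Pmvk 0.45 and 2.82, those of Sod3 2.37 and 0.86, and those of CG15628 0.73 and 1.91. The probes of Drep1 (1.42 and 2.37) and tll (1.71 and 1.77) were all above 2-fold. The 2 arrays correlated at r = 0.01 across genes, with a median distance from the mean of 0.16.

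The early patterning list was again the highest with D168D. Its median was 0.32, with 22 of 26 members above 0, and tll was the 1 member that met the rule. Germline genes were at a median of 0.20 with 19 of 23 members above 0, Hippo pathway genes at 0.16 with 15 of 21 above 0 and cell cycle genes at 0.11 with 17 of 26 above 0. Their percentiles were 99.99, 99.78 and 99.1, and 0 members of these 3 lists met the rule. Oxidative phosphorylation genes lay below the random lists, at -0.10 with 21 of 65 above 0 (percentile 0.77). With D168A the same list was at -0.03 with 23 of 65 above 0, at percentile 3.065 and so inside the central 95%. On the Cy3-driven and Cy5-driven arrays alone it was at percentiles 1.005 and 1.28 with D168A and at 2.485 and 1.52 with D168D. Of the 22 lists, 1.1 are expected outside the central 95% by chance, and the Hippo and cell cycle lists lay inside it on either array alone, at percentiles 87.2 and 93.2 and at 93.5 and 74.6. The germline list lay inside it on the Cy5-driven array alone, at percentile 97.2.

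**Figure D1:**
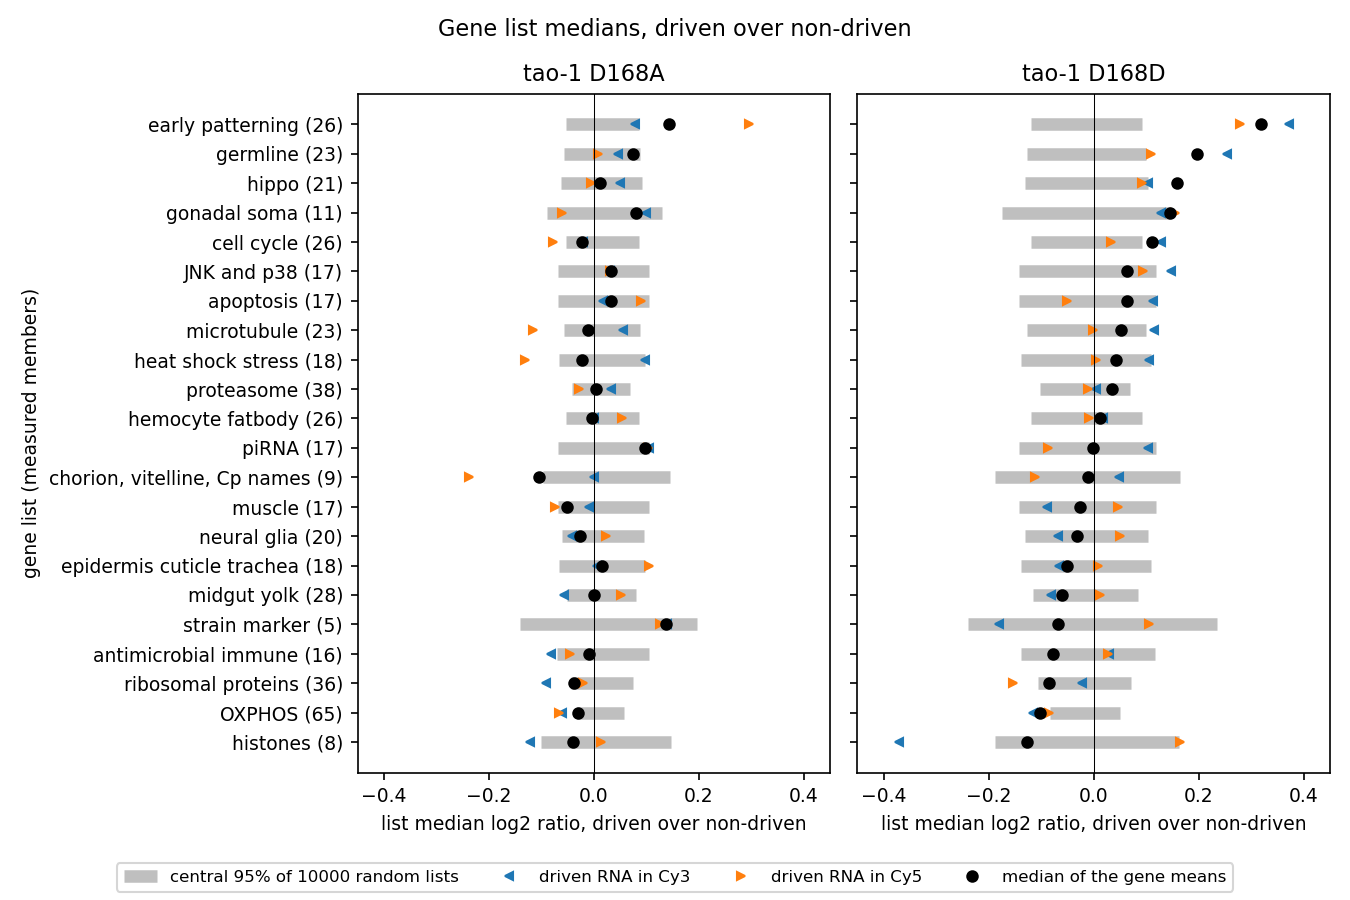
Median log2 ratio, driven over non-driven, of each gene list with D168A (left) and D168D (right), as the median of the gene means (black) and on each array by the dye of the driven RNA. Grey bars span the central 95% of 10000 random lists of the same size; the early patterning list, at 0.14 and 0.32, lies to the right of its bar in both forms.

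Among 17 measured genes of the apoptosis list, 0 met the rule with D168A and 1, Drep1, with D168D, and the list medians were 0.03 and 0.06. The pro-apoptotic gene grim was at 0.34 ± 0.29 with D168A and at -0.03 ± 0.37 with D168D, and 1 of its probes is listed at 0 on an array. The pro-apoptotic gene skl was at -0.30 ± 0.13 with D168A and at 0.38 ± 0.27 with D168D, a difference of -0.68 ± 0.15, and its 2 probes disagreed in sign on the D168D array with driven RNA in Cy3. Neither grim nor skl reached 2-fold in either form.

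The third comparison asked which genes moved in the same direction in both pairs, as the driver, the mothers' genotype or either form of the kinase would make them. In limma over the 2 pairs, 6 genes rose and 0 fell at an adjusted p under 0.05. Tao rose by 2.96 (SE 0.087, adjusted p = 0.00298), bnb by 1.93 (SE 0.085, adjusted p = 0.0117) and Atx-1 by 2.28 (SE 0.117, adjusted p = 0.0168). Pmvk rose by 1.55 (adjusted p = 0.0263), CG6287 by 1.51 and Sod3 by 1.49 (adjusted p = 0.0318 for each). In the mean over their probes, all 6 were higher on 4 of 4 arrays. Over the 4 arrays, however, the probes of CG6287 gave 3.28 and -0.26 and those of Pmvk 0.18 and 2.93. The rise of these genes thus rests on a single probe each. Of the genes that missed the threshold, GstE1 came nearest, at 1.15 with an adjusted p of 0.0593.

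The same 6 genes were those at least 2-fold higher on both arrays of both forms, where independent lists would share 0.0252. There were 0 genes lower in both forms and 0 in opposite directions. An unadjusted p under 0.05 was reached by 1422 genes, 864 higher and 558 lower, against 540.2 expected by chance. The limma count was 3 after centring each array, 15 without genes listed at 0, 0 when tested by probe, and 2 and 0 on the Cy3-driven and Cy5-driven arrays alone. The form means correlated across genes at r = 0.38 and rho = 0.42, genes not being independent replicates, and at r = 0.37 without Tao. Between single arrays of the 2 forms, r ranged from -0.15 to 0.36.

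**Figure D2:**
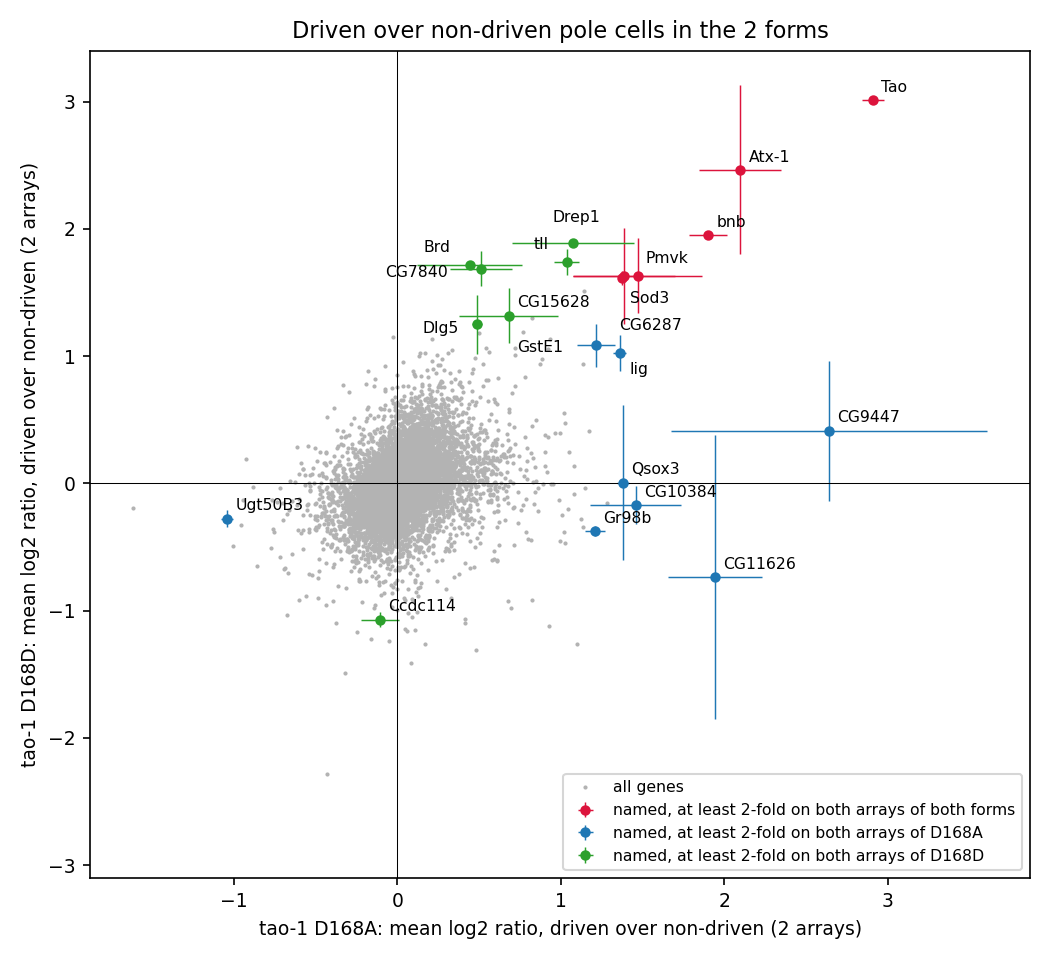
Mean log2 ratio, driven over non-driven, with D168A (horizontal) and D168D (vertical) for all 10804 genes (grey) and for the named genes that met the rule of size in both forms (red), in D168A (blue) or in D168D (green). Bars give the distance of either array from the mean; Tao lies at 2.91 and 3.01, and the other 5 genes in red between 1.38 and 2.46.

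**Figure D3:**
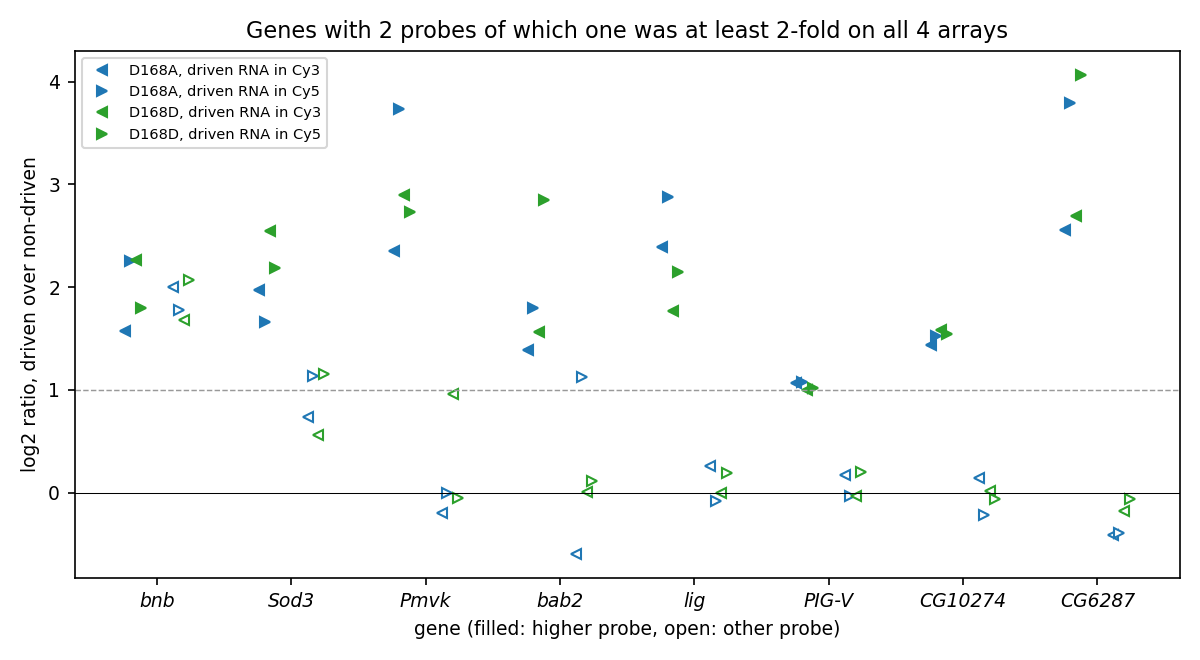
Log2 ratio, driven over non-driven, on each of the 4 arrays for both probes of the 8 genes that have 2 probes of which at least 1 met the rule of size in both forms, without Tao. Filled marks give the higher probe and open marks the other. Colour gives the form (blue D168A, green D168D) and the marker's direction the dye of the driven RNA (left Cy3, right Cy5). In the mean over the 4 arrays, the other probe lay under 0.3 in 6 genes, while the probes of bnb had 1.97 and 1.88.

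The fourth comparison set the forms against each other, which removes what driver and mothers give alike in both pairs. CG11626 was higher with D168A than with D168D by 2.68 ± 1.41, CG4714 by 2.36 ± 0.49, CG9447 by 2.23 ± 0.42, CG10384 by 1.63 ± 0.13 and the gustatory receptor gene Gr98b by 1.58 ± 0.10. The scavenger receptor gene Sr-CI, of the hemocyte and fat body list, was higher by 1.48 ± 0.06. CG15042 (2.05 ± 0.72), the salivary glue gene Sgs1 (1.74 ± 0.09) and CG9168 (1.60 ± 0.25) were also higher, and each is listed at 0 on at least 1 array. On the Cy3-driven and Cy5-driven arrays, Sgs1 was at 1.64 and 0 with D168A and at 0 and -1.83 with D168D. CG9168 was at 1.35 and 0 with D168A and at 0 and -1.85 with D168D. In both genes the arrays of a form thus disagreed, and each non-zero ratio had the Cy3 dye brighter. CG7840 was lower with D168A than with D168D, by -1.18 ± 0.05, and was at 0.51 ± 0.19 and 1.69 ± 0.14 in the forms.

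In all, 14 genes were higher with D168A and 1 was lower, against 14 that met the same rule with the sign of the Cy3-driven arrays restored. Treated as 4 replicate arrays, limma called 0 genes, with 230 at an unadjusted p under 0.05, fewer than the 540.2 expected by chance. Among the lists, germline (-0.15), early patterning (-0.16), gonadal soma (-0.15) and cell cycle genes (-0.08) were lower with D168A than with D168D, outside the central 95% of random lists. On the Cy5-driven arrays alone the early patterning list was at percentile 39.6, on the Cy3-driven arrays alone the gonadal soma list was at 54.3, and the cell cycle list lay inside the range on either alone, at 3.93 (Cy3) and 10.5 (Cy5).

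Markers of other cell types that the sort could hold stayed inside the central 95% in both forms. The medians with D168A and D168D were -0.05 and -0.03 for muscle, -0.03 and -0.03 for neurons and glia, 0.02 and -0.05 for epidermis, cuticle and trachea, -0.00297 and 0.01 for hemocytes and fat body, and 0.00089 and -0.06 for midgut and yolk. The gonadal soma list was at 0.08 and 0.14, and with D168D it lay at the edge of that range, at percentile 97.465 with 9 of 11 members above 0. Other lists inside that range in both forms were the piRNA pathway (0.10 and -0.00199), JNK and p38 kinases (0.03 and 0.06), microtubule genes (-0.01 and 0.05), antimicrobial genes (-0.01 and -0.08), ribosomal proteins (-0.04 and -0.09), proteasome subunits (0.0047 and 0.03), histones (-0.04 and -0.13) and markers of laboratory strains (0.14 and -0.07). Of the 8 strain markers, 5 were measured. The genes y and w were not among them, so the list is no check of the mothers' yw genotype. Heat shock and stress genes (-0.02 and 0.04) held GstE1, the 1 member that met the rule with D168A. Some of these lists left that range on a single array. With D168A these were the piRNA (percentile 97.73) and ribosomal lists (0.48) on the Cy3-driven array, and the microtubule (1.38) and stress lists (1.33) on the Cy5-driven array. With D168D they were the histones on the Cy3-driven array (0.76) and the ribosomal proteins on the Cy5-driven array (0.23). The mean and the median of a list differed in sign for the microtubule and stress lists with D168A, the piRNA list with D168D, and the hemocyte and proteasome lists with both. After centring each array, the midgut and proteasome medians with D168A changed sign, to -0.0065 and -0.0027.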

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

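The test of deposited zeros was chosen after the genes had been seen. The differences between the forms given here were not tested, since each form is 1 replicate.

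Genes and lists are described here because both arrays of D168A lay on one side of 0 and both arrays of D168D on the other. Over all genes, 530 of 10804 (4.91%) have that pattern, against 12.5% if the signs were random. Among the named genes it held for CG4714, which was at 1.10 with D168A and -1.26 with D168D, a difference of 2.36. It also held for CG10384 (1.46 and -0.17, difference 1.63) and for Gr98b (1.21 and -0.37, difference 1.58). Sr-CI, a hemocyte marker, was at 0.41 and -1.06, a difference of 1.48. The pro-apoptotic gene skl went the other way, at -0.30 with D168A and 0.38 with D168D, a difference of -0.68. Its 2 probes gave 0.43 and -0.21 on the D168D array with driven RNA in Cy3, so the sign there rests on 1 probe. For the cell cycle list the median difference was -0.084. The antimicrobial list had array medians of -0.08 and -0.04 with D168A and of 0.03 and 0.03 with D168D, but its median over gene means was below 0 in both forms (-0.01 and -0.08). Its median difference of 0.036 was at percentile 58.03 of random lists and had no settled direction, at -0.12 on the Cy3-driven arrays and 0.006 on the Cy5-driven arrays.

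Among the 15 genes that differ at least 2-fold between the forms, 4 (26.7%) have a deposited 0 on some array, against 4.36% of all genes (Fisher's exact test, one-sided, p = 0.00332). For CG15042, CG15353, CG9168 and Sgs1, dim spots whose ratio was set to 0 are therefore a candidate explanation, and the other 11 genes have no such value. Every one of the 15 differs 2-fold in either dye orientation by the rule itself, so a fault of 1 array cannot by itself account for a call. Variation between hybridisations stays open, since 14 genes met the rule with the sign restored, and so does the kinase form, untested.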

How the results depend on the processing

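The demand that every probe pass and the lists without called members were chosen after seeing the data. Unless a reason is given, the cause was not tested. Counts are higher and lower genes in driven cells with D168A, with D168D, and for D168A against D168D, where the reported ones are 16 and 1, 17 and 1, and 14 and 1. By construction, 1.5-fold gave 54 and 8, 83 and 34, and 59 and 30, where 85, 73 and 205 genes met it with the sign restored, more than were called with D168A (62) and for the difference (89). At 3-fold there were 5 and 0, 6 and 0, and 3 and 0, against 1, 0 and 0 with the sign restored. The mean of both arrays alone gave 32 and 3, 32 and 21, and 58 and 8. Counting probes gave 28 and 4, 39 and 1, and 24 and 5. A single dye orientation gave 42 to 214 and 24 to 51 with D168A, 68 to 80 and 40 to 128 with D168D, and 47 to 360 and 78 to 87 for the difference. limma over the 4 arrays as replicates gave 3 and 0, 7 and 0, and 0 and 0 (312, 715 and 230 genes at an unadjusted p under 0.05, where 540.2 are expected by chance). Read as log2, the values gave 0 and 0 throughout, since every ratio shrinks.

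Subtracting the other form's dye effect gave 12 and 0 with D168A and 13 and 2 with D168D, with 10 of 17 and 14 of 18 called genes kept. Across genes, the dye components of the forms correlated only at r = 0.10 and rho = 0.06. What is subtracted is therefore largely not shared by the forms, and a lost call cannot be put down to dye. With every probe required to pass, 12 and 0 and 10 and 1 genes were left in the forms, and 12 and 1 for the difference. Genes with 1 probe pass by construction, and of the called genes with more probes 2 of 7, 5 of 12 and 0 of 2 were kept. The genes lost were CG6287, Pmvk, Sod3, lig and Ugt50B3 with D168A, CG6287, Pmvk, Sod3, CG15628, Dlg5, CG12159 and Lapsyn with D168D, and 5-HT1A and CG10175 for the difference. Centring kept all called genes in the 3 comparisons, and leaving out genes with a deposited 0 left 14 and 1, 17 and 1, and 10 and 1.

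The 6 genes of the common contrast became 3 after centring, 15 without genes with a deposited 0 and 0 by probe. They became 0 to 2 on a single dye orientation, 6 with robust moderation and 4 over the 4 arrays, and 0 genes fell under any of these. At an unadjusted p under 0.05 there were 1364, 1534, 1942, 1134 (Cy3), 783 (Cy5), 1395 and 878.

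Lists below the random range became 2 to 4 with D168A on a single dye orientation and 3 by the mean in place of the median, where the egg-shell list is lost (percentile 7.76) and ribosomal proteins (0.84), oxidative phosphorylation (1.71) and histones (2.4) enter. With D168D they became 2 either way, and for the difference 2 to 4 and 8. Lists above it with D168D became 1 to 2 on a single orientation and 6 by the mean, which adds the apoptosis (percentile 99.2) and the heat shock and stress list (99.8). Among the lists outside the random range, 2 medians changed sign with driven RNA in Cy3 alone. The egg-shell list with D168A went from -0.10 to 0.0010 (-0.24 on Cy5 alone), and the gonadal soma list in the difference from -0.15 to 0.034 (-0.33 on Cy5 alone). Several lists inside the range changed sign as well. The heat shock and stress list with D168A, for example, went from -0.02 to 0.10 (-0.13 on Cy5 alone).

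The correlation of the forms was 0.62 over the 2447 genes with the same sign on both arrays of each form, which selects for agreement. It was -0.15 between D168A with driven RNA in Cy3 and D168D with it in Cy5, 0.30 for the other opposite pair, and 0.36 and 0.15 for the same dye. Tao with D168D was at 3.16 and 2.87 by probe. No paired analysis was possible because the groups share fewer than 2 replicate numbers and each form is 1 replicate. Signal over background is unknown, so dim genes could not be separated. Leaving out a whole pair leaves no residual degrees of freedom.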

Other observations

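The tests of a single probe, of bnb and Sod3, of the mothers' genotype, of differentiated somatic cells, of a few members of the early patterning list and of embryo age were chosen after the result was seen. That of a few members replaced an earlier removal of tll alone, which can hardly move a median.

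Below the threshold of the common contrast lay further genes that were higher with both forms, named here after their values were seen. SNCF was at 1.33 (SE 0.117), bab2, a transcription factor gene, at 1.03 (SE 0.095), CG33137 at 1.04 and CG17109 at 0.99. With lig (1.19), tun (0.93) and CG11263 (0.90), they share an adjusted p of 0.0802 in limma over the 2 pairs. The probes of bab2 gave 1.90 and 0.16 over the 4 arrays. Of the 16 genes higher with D168A, 12 had a mean above 0 with D168D, and of the 17 higher with D168D all 17 had a mean above 0 with D168A. Both counts include the 6 genes called in both forms, which are above 0 in the other form by definition. The genes called in 1 form only were 10 with D168A and 11 with D168D. Across all genes, 1900 (17.6%) had the same sign on all 4 arrays, against 12.5% for random signs.

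Genes higher with both forms were weighed against a difference at 1 probe of the gene, such as a strain variant under the probe or another transcript end. In 8 genes with 2 probes of which at least 1 met the rule of size in both forms, the other probe had a median of 0.127, and it lay under 0.3 in 6, among them Pmvk, CG6287, lig and bab2. For these a probe-specific difference between the mothers' strains may account for the ratio, while for bnb and Sod3 the lowest probe was at 0.897, which argues against it. The mothers' genotype as the source of all ratios but that of Tao stays open, because the mothers are the same in both pairs. The 5 genes differed between the forms by a median of 0.238, and the median distance of an array from its form's mean was 0.274. The former is a full difference and the latter a distance from a mean, so they are unlike measures. The genes were also chosen for passing in both forms, which favours a small difference in advance. The values therefore do not bear on the source, and an effect of either kinase form cannot be told apart from that of the driver.

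The early patterning list, whose median lay above random lists in both forms, was weighed against more differentiated somatic cells in the driven sort. The 107 pooled markers of muscle, nerve, epidermis, hemocytes and midgut had 47 and 48 members above 0 with D168A and D168D. The upper 95% bootstrap bound of their median was at most 0.0174, below the list's 0.14 and 0.32. That bound covers variation over markers and none between sorts. No signal level was used, so how many of the markers were expressed at these stages is unknown. A marker without expression would lie near 0 whatever cells were sorted, and Mal-A1 is listed at 0 on every array. The pooled median therefore cannot decide on differentiated somatic cells. Without its 5 highest members the list's median was 0.10 with D168A and 0.18 with D168D, at percentiles 98.25 and 99.94 of random lists of 21 genes that lost none, which argues against a few members as the source. Undifferentiated cells of the early soma were not covered by the pooled markers. These leave out the muscle gene twi because it is also a patterning gene. Undifferentiated and differentiated somatic cells both stay open, as do expression of the kinase and the driver. A younger driven collection could also give the 0.319 seen with D168D, and it cannot be told apart because stage is not recorded by sample.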
